A study of Homo sapiens with 8 samples.

How the data were processed

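RNA of EPC2-hTERT cells, grown in keratinocyte serum-free medium with epidermal growth factor and bovine pituitary extract and kept for 24 hours in hypoxia or at 21% O2, was purified on RNeasy columns, labelled as biotin cRNA and hybridised to Affymetrix HG-U133 Plus 2 arrays, per the labels' protocols. The 8 arrays fall into 4 groups of 2: normoxia and hypoxia in each of 2 experiments. The sources used here contradict each other on which experiment was at 1% and which at 0.2% O2, so none of the comparisons assigns a level. The deposited values were made with GCRMA (background correction by probe sequence, quantile normalization and median polish) and Partek 6.4, per the submitters' processing notes. They were taken as log2 expression values: the log base of the deposited values is not given in the sources used here, and log2 was inferred from their range. If the base were different, every log2 difference would rescale, while directions would stay.

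The deposited table held 35166 probe sets, of which 19187 had values in both experiments, 2061 in experiment 1 only, 9986 in experiment 2 only and 3932 in none. Blanks covered whole experiments, and their cause is not given in the sources used here. Between 44.0% and 44.8% of the values on each experiment 1 array and between 30.4% and 30.6% on each experiment 2 array lay under log2 4. Of the probe sets with values, 25029 were linked to 1 gene symbol (25014 matched the RefSeq gene table), and 1178 with several symbols, 4968 with none and 59 control probe sets were left out of the gene tests. Probe sets were kept where at least 2 of the 8 arrays exceeded log2 4 (18204 with 1 symbol), and each gene was read from its probe set with the highest mean. This left 8588 genes in experiment 1, 10041 in experiment 2 and 8487 in both. A fold with 1 group under log2 4 is given as a bound, with that group's mean raised to 4. For no named gene is a direction given where both groups lay under log2 4. The counts of calls keep such genes: 19 higher and 91 lower in experiment 1, and 1 higher and 0 lower in experiment 2.

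Gene tests used limma 3.58.1 in R 4.3.3: a fit with 1 mean per group on all 8 arrays, empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes tested, with calls at adjusted p under 0.05. The contrasts were hypoxia minus normoxia in experiment 1, in experiment 2 and in their mean, and the difference between the experiments (experiment 2 minus experiment 1). Tests were two-sided. With 2 arrays against 2, an exact permutation test of 1 gene could not go below p = 0.333, so the calls rest on the spread pooled across genes and groups. A set of 28 gene lists was tested with limma's camera at a preset correlation of 0.01 where at least 5 members were measured, and beside it with the correlation estimated per list. With the estimated correlation limma's camera called 0 lists in experiment 1, in experiment 2 and in the difference, and 4, 5 and 4 lists had an unadjusted p under 0.05. The fry test, which asks whether the members move one way on balance without comparing them with other genes, was run as well and called 20, 11 and 16 lists. Lists covered glycolysis, other HIF targets, HIF pathway components, prostaglandins, the IGF axis, squamous and basal keratinocyte genes, Notch, mesenchymal genes, DNA replication, G2/M, unfolded protein and integrated stress response, sterol synthesis, oxidative phosphorylation, the tricarboxylic acid cycle, interferon, NF-kB, p53, autophagy, collagen modification, NRF2, ribosome biogenesis, JmjC demethylases, MAPK feedback, and fibroblast, endothelial, leukocyte and columnar markers. The groups, contrasts, filter, tests, lists and the rule for naming genes were chosen before the data were examined.

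Genes are named by this rule: in experiment 1, in experiment 2 and in their mean, the 10 largest rises and 10 largest falls in log2 among called genes with both hypoxia arrays on the same side of both normoxia arrays in each experiment concerned; for the difference, the 10 largest in size; up to 4 members per list with the smallest p for the mean; and HIF1A, EPAS1, ARNT, VEGFA, CA9, SLC2A1, PTGS2, PTGES and IGFBP3. Any other gene is said to be named after its values were seen, is cited as an example of a list added later, or, as GAPDH and ACTB, serves as a control of RNA quality.

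The tests were tried on simulated data built from each gene's mean and spread in each experiment. For experiment 1, 96.5% of genes changed by 1 log2 unit and 64.4% of those changed by 0.5 were recovered, and 1.04% of 8328 unchanged genes were called. For experiment 2 the shares were 98.5%, 36.9% and 0.0508% of 9843. For the mean of both, 89.0% of changes of 0.5 were recovered, and for the difference 69.3% of changes of 1. Of simulated lists, 0 of 20 unchanged and 5 of 5 raised by 0.5 were called. The simulated genes varied independently, while the estimated correlation within the real lists reached 0.70 (G2/M). The simulation therefore cannot show whether the preset correlation of 0.01 limits false list calls here. The experiments share 1 estimate of spread, and the unchanged genes of experiment 1 were called more often than those of experiment 2. The simulated calls of experiment 1 held 87 unchanged genes beside 38, 138 and 58 genes changed by 0.5, 1 and 2. False calls there thus exceeded the nominal share of 0.05, in a simulation where few genes changed. In experiment 2 the unchanged genes called numbered 5, and with experiment 1 fitted alone 7. Alternatives covered the level filter, values under log2 4 set to 4, median centring, quantile normalization, the variance model, each experiment fitted alone, a replicate block, an additive fit, thresholds of 0.01 and 2-fold, the choice of probe sets, list tests, and each array left out, where the lone array of a group was assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.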

Results

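The cells were EPC2-hTERT, a line of normal human esophageal keratinocytes kept dividing by telomerase and not transformed. RNA was measured on 8 whole-transcriptome expression arrays after 24 hours in hypoxia or at 21% O2 (normoxia). There were 2 experiments, each with its own normoxia control, and 2 arrays in each of the 4 groups. The design statement and the treatment protocol assign the hypoxia levels, 1% and 0.2% O2, to the experiments in opposite order, so the experiments are named only by number and no result is tied to an oxygen level. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. Values were present for 21248 probe sets in experiment 1 and 29173 in experiment 2. The array medians in experiment 1 were 5.03 and 5.08 in normoxia and 5.01 and 4.91 in hypoxia, in log2 units. Those in experiment 2 were 6.86 and 6.88 in normoxia and 6.82 and 6.87 in hypoxia. Because the distributions of the experiments differ, only differences within an experiment were compared. The Pearson correlation between replicates, across the genes tested with 1 probe set each, was 0.997 in normoxia and 0.996 in hypoxia in experiment 1. In experiment 2 it was 0.997 and 0.998.

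Which genes responded to 24 hours of hypoxia in experiment 1? The largest rises were in genes that hypoxia-inducible factors (HIF) switch on: ANKRD37, the prolyl hydroxylase EGLN3 that marks HIF for degradation, the mitochondrial protein gene COXFA4L2 (formerly NDUFA4L2), the glycolytic enzyme ENO2, PDK1, which holds pyruvate back from the mitochondria, and the lipase inhibitor ANGPTL4. The inducible prostaglandin E synthase PTGES and the neutrophil chemokine CXCL8 rose as well. The largest falls included MAT2A, which makes the methyl donor S-adenosylmethionine, the suprabasal keratin KRT13, and asparagine synthetase ASNS, and the transferrin receptor TFRC also fell. Of 8588 genes tested, 1378 were higher and 2145 lower in hypoxia, 41.0% of the total, and 513 and 907 of them changed at least 2-fold. Counted in are 19 higher and 91 lower with both groups under log2 4, for which no direction is given. With experiment 1 fitted alone, so that no spread came from experiment 2, 2200 genes were called against 3523. In the simulated data the fit of all 8 arrays called 87 unchanged genes in experiment 1. With experiment 1 fitted alone it was 7. EGLN3 rose by 9.80 ± 0.14 log2 units (SE, 2 arrays per group; adjusted p = 2.25e-07). Its normoxia mean lay under log2 4, a level where arrays measure mostly background, so the change is given as at least 545-fold. ANKRD37 rose by 9.94 ± 0.18 (at least 303-fold; adjusted p = 4.09e-07) and COXFA4L2 by 8.75 ± 0.17 (at least 210-fold; adjusted p = 5.38e-07). ENO2 rose at least 98.4-fold, ANGPTL4 at least 153-fold, PPP1R3C at least 88.4-fold and PTGES at least 102-fold. PDK1 rose at least 150-fold (adjusted p = 3.01e-07) and KRTAP19-1, a hair keratin-associated protein gene, at least 209-fold (adjusted p = 2.19e-08). CXCL8 rose at least 51.2-fold, but a second probe set of CXCL8 changed by 0.08 log2 units. MAT2A fell by 6.55 ± 0.12 on the log2 scale, at least 58.1-fold (adjusted p = 4.09e-07). ASNS was at least 35.9-fold lower, KRT13 59.5-fold lower (adjusted p = 0.000478) and TFRC 32.9-fold lower. The remaining falls among the 10 largest were in PAFAH1B1, BRI3BP, FOXQ1, DAPL1, ISG20L2, PRMT3 and PPIL1, with bounds from -5.37 (BRI3BP) to -4.05 (PPIL1) log2 units. For each of these genes both hypoxia arrays lay on the same side of both normoxia arrays, and each kept its call with any 1 of the 8 arrays left out. Of 40 named genes with at least a 2-fold change here and another probe set above log2 4, 14 had one that changed less than 1/2 as much on the log2 scale or in the opposite direction: ANGPTL4, ARG2, ATF3, CENPF, CXCL8, DLL1, HES1, HPGD, KDM4B, PAFAH1B1, PDHA1, PDK1, PTGES and SOX2.

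The hypoxia programme moved almost as a block in experiment 1. Of 23 glycolysis and glucose uptake genes 22 rose and 1 fell, the same adjusted over the list alone (adjusted p = 6.22e-14 for the list; adjusted p = 0.0844 with an estimated correlation). HK2, which commits glucose to the cell, rose by 2.99 log2 units, ALDOC by 2.55 and the glucose transporter SLC2A1 1.92-fold (adjusted p = 0.000115), with its second probe set at 2.18 log2 units. Of 30 other HIF target genes 28 rose and 1, TFRC, fell, the same adjusted over the list alone (adjusted p = 8.75e-21; adjusted p = 0.0844 with an estimated correlation). Among them the mitophagy gene BNIP3L rose by 2.88, TMEM45A by 4.08 and VEGFA, the angiogenic factor, by 0.54 (adjusted p = 0.0115, and 0.0787 with experiment 1 fitted alone). Collagen and matrix modification genes rose in 8 and fell in 1 of 13, or 9 and 2 adjusted over the list alone (adjusted p = 0.000756; adjusted p = 0.268 with an estimated correlation). The collagen hydroxylases P4HA1 and PLOD2 rose by 3.18 and 3.30, and the lysyl oxidase LOXL2 by 3.74. Sterol synthesis genes rose in 14 of 16, or 15 adjusted over the list alone (adjusted p = 7.45e-08; adjusted p = 0.0902 with an estimated correlation), with IDI1 at 1.42, SC5D at 1.51 and ACAT2 at 0.96. NF-kB targets and cytokines rose in 7 of 12 and fell in 0, or 7 and 1 adjusted over the list alone (adjusted p = 0.000756; adjusted p = 0.268 with an estimated correlation). TNFAIP3, which restrains NF-kB, rose by 3.39, NFKBIA by 1.69 and IL1B by 1.23. The list lost its call without probe sets that can bind several transcripts (adjusted p = 0.222).

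Several lists of differentiation, growth and stress response genes shifted down in experiment 1 at the preset correlation, though not every member fell. Of 34 squamous differentiation genes, which mark cells leaving the basal layer, 11 were measured. Of these 11, 9 fell and 0 rose, the same adjusted over the list alone (adjusted p = 0.000149; adjusted p = 0.268 with an estimated correlation). S100A8 fell by 3.20 on the log2 scale, SPRR1A by 2.72 and the cornified envelope protein PPL by 1.75. DNA replication genes fell in 13 of 24, the same adjusted over the list alone (adjusted p = 0.000992; adjusted p = 0.365 with an estimated correlation), with MCM6 at -1.61, RFC3 at -1.97 and UNG at -1.60. CDC6 and GINS2, named after their values were seen, are counted among the 13 although both of their groups lay under log2 4, so no direction is given for them. Unfolded protein and integrated stress response genes fell in 16 and rose in 3 of 23, the same adjusted over the list alone (adjusted p = 0.0029; adjusted p = 0.266 with an estimated correlation). The amino acid synthesis gene PSAT1 fell by 2.75 on the log2 scale, while ATF3, an immediate stress factor, rose at least 7.80-fold and PPP1R15A by 2.69. A second probe set of ATF3 changed by 0.02 (adjusted p = 0.972 when used instead). NRF2 antioxidant genes fell in 8 of 12, the same adjusted over the list alone (adjusted p = 0.000774; adjusted p = 0.306 with an estimated correlation). SLC7A11, the cystine importer, changed by -3.89, and the glutathione synthesis genes GCLC and GCLM by -2.53 and -1.69. Ribosome biogenesis genes fell in 9 and rose in 1 of 12, the same adjusted over the list alone (adjusted p = 0.00588; adjusted p = 0.255 with an estimated correlation), with WDR43 at least 3.40-fold lower and WDR12 at -1.94. The polyamine synthesis gene ODC1 changed by -4.75, and SRM was at least 11.4-fold lower.

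The lists of oxidative phosphorylation and tricarboxylic acid cycle genes shifted down too. Oxidative phosphorylation genes fell in 15 and rose in 1 of 25, or 15 and 2 adjusted over the list alone (adjusted p = 0.00607; adjusted p = 0.424 with an estimated correlation), with CYCS, the electron carrier cytochrome c, at -1.69, SDHD at -0.99 and ATP5F1B at -0.89. Tricarboxylic acid cycle genes fell in 7 of 15, or 8 adjusted over the list alone (adjusted p = 0.0357; adjusted p = 0.424 with an estimated correlation), among them IDH3A at -3.21 and PDP1 at -1.79. That list call ended without normoxia replicate 2 of experiment 1 (adjusted p = 0.065) and without probe sets that can bind several transcripts (adjusted p = 0.0639). Autophagy and lysosome genes rose in 7 and fell in 1 of 18, the same adjusted over the list alone (adjusted p = 0.0388; adjusted p = 0.365 with an estimated correlation). ULK1, which starts autophagy, rose at least 5.67-fold, OPTN by 1.11 and ATG5 by 0.80. The autophagy call ended without normoxia replicate 1 (adjusted p = 0.053), without hypoxia replicate 1 (adjusted p = 0.0814) and after quantile normalization (adjusted p = 0.0728). It also ended where at least 2 arrays had to exceed log2 6 (mean 0.12; adjusted p = 0.139) and with values under log2 4 set to 4 (adjusted p = 0.0507). JmjC histone demethylases, enzymes that need oxygen to strip methyl groups from histones, rose in 5 and fell in 2 of 14, or 5 and 3 adjusted over the list alone (adjusted p = 0.0357; adjusted p = 0.266 with an estimated correlation). KDM3A rose by 5.56 and KDM4B by 3.17, though without probe sets that can bind several transcripts KDM4B changed by 0.26. KDM4C, named after its values were seen and counted as a rise, had both groups under log2 4. The JmjC call ended without normoxia replicate 2 (adjusted p = 0.054), without hypoxia replicate 2 (adjusted p = 0.0975) and with the arrays centred on their median (adjusted p = 0.051). It also ended without probe sets that can bind several transcripts (mean 0.06; adjusted p = 0.288) and with values under log2 4 set to 4 (adjusted p = 0.103).

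The other lists were not called in experiment 1. Basal keratinocyte genes rose in 5 and fell in 2 of 15 (adjusted p = 0.192), with the receptor EGFR at 1.36, ITGB4 at 0.75 and the stem cell factor SOX2 at -2.48. Notch pathway genes rose in 5 and fell in 2 of 15 (adjusted p = 0.0762), including the ligand DLL1 at 1.96 and its target HES1 at 2.99. Mesenchymal and EMT genes rose in 7 and fell in 3 of 15 (adjusted p = 0.0762), with MMP2 at 0.59, TGFBI at 0.68 and TWIST2 at -1.72. G2/M genes rose in 1 and fell in 6 of 27, or 1 and 4 adjusted over the list alone (adjusted p = 0.728): CDC20 changed by -1.50, CCNA2 by -1.75 and CENPF by 1.14, where a second probe set of CENPF changed by -0.31. The CENPF call ended with the mean of its probe sets (adjusted p = 0.0959) and with experiment 1 fitted alone (adjusted p = 0.0541), as did that of OAS2 in the latter (adjusted p = 0.0601). Interferon response genes rose in 1 and fell in 4 of 18 (adjusted p = 0.662), with IRF7 at 1.56 and OAS2 at -1.90. p53 targets rose in 4 and fell in 5 of 15 (adjusted p = 0.825), with DDB2 at 1.61, GADD45A at 0.90 and MDM2 at -1.23. The median of the p53 list was -0.21 and its mean -0.08, while its test pointed up. MAPK and EGFR feedback genes rose in 3 and fell in 4 of 13, or 3 and 7 adjusted over the list alone (adjusted p = 0.958). Here the phosphatase DUSP1 rose by 5.16 (adjusted p = 4.09e-07) and IER3 by 2.49, while the EGFR ligand EREG changed by -4.37 and PHLDA1 by -1.17. For the basal, Notch, mesenchymal, interferon and p53 lists the counts were the same adjusted over the list alone.

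**Figure D1:**
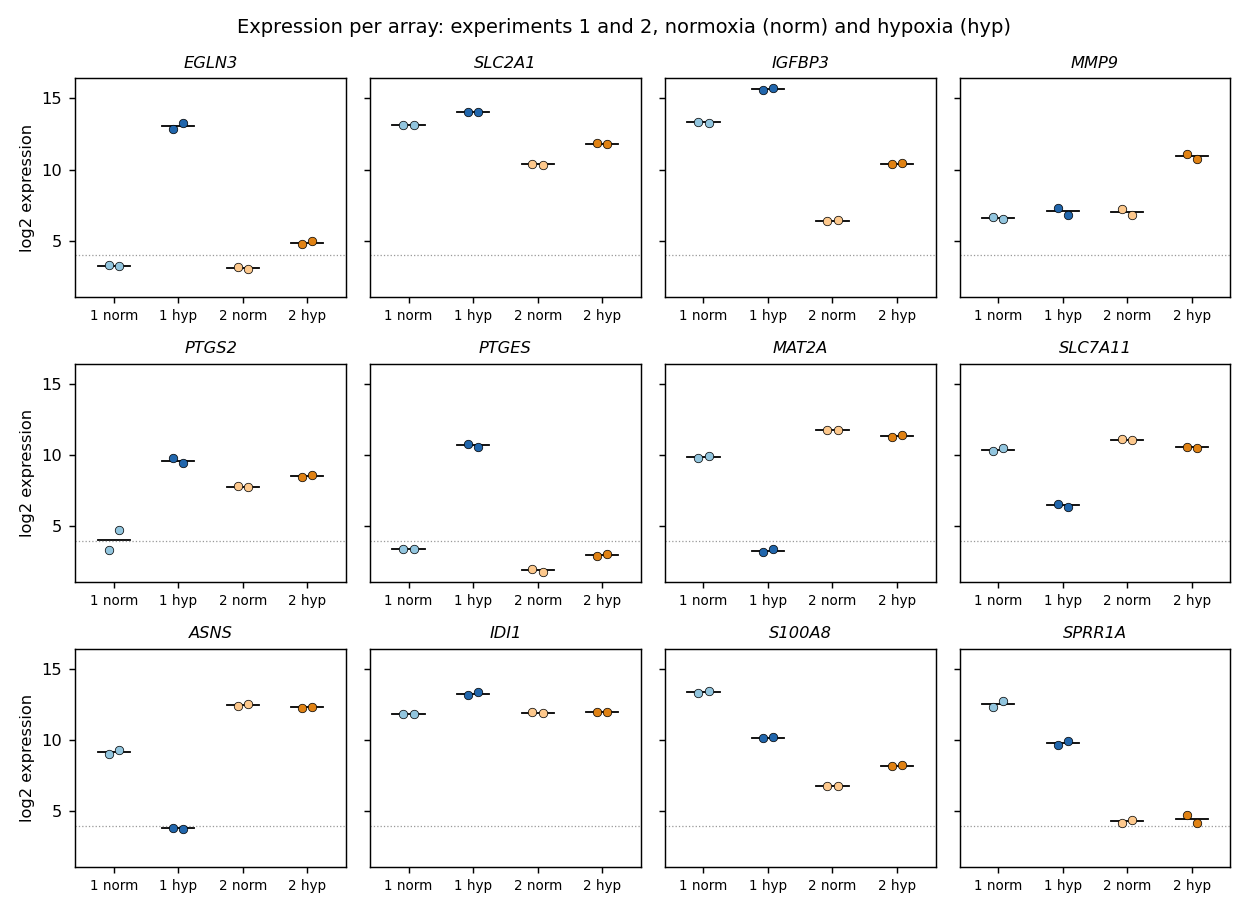
Each panel plots 1 gene, with log2 expression on the y axis and the groups on the x axis; points are the 2 arrays of each group, the line is their mean and the dotted line is log2 4. EGLN3 rises from under log2 4 in both experiments, while IGFBP3 rises by 2.32 log2 units in experiment 1 and 4.01 in experiment 2.

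Which genes responded in experiment 2? COXFA4L2 rose again, and IGFBP3, which binds insulin-like growth factors, the gelatinase MMP9, the decoy receptor IL1R2 and the host gene of a hypoxia-induced microRNA, MIR210HG, were among the largest rises. Most glycolysis and HIF target genes rose. The falls were smaller and included the mitochondrial fatty acid importer CPT1A, the glutathione peroxidase GPX2, the envelope protein PPL and ADAMTSL1. Of 10041 genes tested, 375 were higher and 357 lower in hypoxia, 7.29% of the total, with 105 and 28 changed at least 2-fold and 2446 genes at an unadjusted p under 0.05. Among those higher, 1 had both groups under log2 4. These counts rested on each array: without normoxia replicate 1 they were 127 and 81, without normoxia replicate 2 108 and 34, without hypoxia replicate 1 70 and 22, and without hypoxia replicate 2 99 and 75. The processing moved the total of 732 calls as well. It was 1447 after quantile normalization, 1538 with experiment 2 fitted alone and 110 with a replicate block. COXFA4L2 rose by 7.40 ± 0.17 log2 units (SE, 2 arrays per group; at least 122-fold; adjusted p = 9.71e-06). IGFBP3 rose 16.1-fold (4.01 ± 0.08; adjusted p = 8.86e-06). MMP9 rose 14.9-fold (3.90 ± 0.22; adjusted p = 0.000511), IL1R2 8.25-fold (adjusted p = 0.000419), DEPP1 6.92-fold (adjusted p = 0.000699) and ANKRD37 by 2.85 log2 units. The uncharacterized LOC154761 rose at least 5.48-fold (adjusted p = 7.93e-05), and CTHRC1, a secreted matrix protein gene, at least 4-fold (adjusted p = 0.00159). MIR210HG rose 9.86-fold (adjusted p = 0.00728) and ENO2 at least 6.91-fold (adjusted p = 0.0139). Among the falls, MATR3 was 3.37-fold lower (adjusted p = 0.00266), SLC35G1 3.01-fold lower (adjusted p = 0.000376) and GPX2 2.42-fold lower (adjusted p = 0.00129). ADAMTSL1 was 4.01-fold lower (adjusted p = 0.0368), while CLN6 changed by -1.66, TMEM201 by -1.59, CPT1A by -1.36 (adjusted p = 0.0139), FOXA2 by -1.25 and PPL by -1.25, and NCR3LG1 was at least 1.41-fold lower. Other probe sets of ADAMTSL1 and CLN6 changed by -0.60 and 0.03. Both hypoxia arrays lay on the same side of both normoxia arrays for each of these genes. Of the 20, 11 kept their call with any 1 of the 8 arrays left out. Without any 1 of the 4 arrays of experiment 2 the calls of ENO2 and PPL ended (adjusted p up to 0.127 and 0.163). The MIR210HG call ended without either hypoxia array of experiment 2 (up to 0.0993) and the NCR3LG1 call without hypoxia replicate 1 (0.0584). The calls of TMEM201 and CPT1A ended without either normoxia array or hypoxia replicate 1 (up to 0.139 and 0.105), and the FOXA2 call without normoxia replicate 2 or either hypoxia array (up to 0.238). The calls of ADAMTSL1 and CLN6 ended without any normoxia array of either experiment, and that of CLN6 also without hypoxia replicate 1 of experiment 2 (up to 0.173 and 0.198). Without a level filter the calls of ADAMTSL1, CLN6 and FOXA2 ended (adjusted p = 0.0592, 0.0781 and 0.0728), and that of CLN6 with experiment 2 fitted alone (adjusted p = 0.0518).

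Glycolysis and HIF target genes also led the lists in experiment 2. Glycolysis and glucose uptake genes rose in 19 and fell in 1 of 23, or 20 and 1 adjusted over the list alone (adjusted p = 1.66e-18; adjusted p = 0.0706 with an estimated correlation). SLC2A1, which carries glucose into the cell, rose 2.76-fold (adjusted p = 0.000376; second probe set 1.84 log2 units), and ALDOC by 1.46 log2 units. Other HIF target genes rose in 23 and fell in 1, TFRC, of 31, or 27 and 1 adjusted over the list alone (adjusted p = 1.96e-24; adjusted p = 0.0706 with an estimated correlation). Among them P4HA1 rose by 1.91, BNIP3L by 1.83, TMEM45A by 1.59 and PLOD2 by 1.22. Collagen and matrix modification genes rose in 5 of 14 and fell in 0, or 5 and 1 adjusted over the list alone (adjusted p = 3.64e-05; adjusted p = 0.268 with an estimated correlation). JmjC histone demethylases rose in 4 of 15, the same adjusted over the list alone (adjusted p = 4.4e-05; adjusted p = 0.0776 with an estimated correlation), KDM4B by 1.15 and KDM5B by 0.49. Mesenchymal and EMT genes rose in 4 of 15 and fell in 0, or 7 and 2 adjusted over the list alone (adjusted p = 9.4e-05; adjusted p = 0.342 with an estimated correlation, and 0.0535 without probe sets that can bind several transcripts), among them MMP9, MMP2 at 0.80 and TGFBI at 0.41. NF-kB targets rose in 3 of 16, or 4 adjusted over the list alone (adjusted p = 0.00142; adjusted p = 0.394 with an estimated correlation): TNFAIP3 by 0.82, with ICAM1 and TNF, the latter pair named after their values were seen. The NF-kB call ended without probe sets that can bind several transcripts (mean 0.21; adjusted p = 0.145). Ribosome biogenesis genes, which build the protein factories of growing cells, fell in 8 of 17, or 10 adjusted over the list alone (adjusted p = 3.81e-07; adjusted p = 0.0857 with an estimated correlation), with WDR43 at -0.82, WDR12 at -0.80 and NOP58 at -0.60. NRF2 antioxidant genes fell in 5 of 12, or 9 adjusted over the list alone (adjusted p = 5.76e-06; adjusted p = 0.246 with an estimated correlation), with GCLM at -0.85, GCLC at -0.61 and SLC7A11 at -0.54. Oxidative phosphorylation genes fell in 1 of 25, ATP5F1B at -0.48, or 5 adjusted over the list alone (adjusted p = 1.15e-05; adjusted p = 0.342 with an estimated correlation). The single-gene calls of WDR43, WDR12, NOP58, GCLM, GCLC, SLC7A11, ATP5F1B, TNFAIP3, KDM4B, KDM5B, MMP2 and TGFBI had adjusted p up to 0.121, 0.244, 0.189, 0.17, 0.146, 0.188, 0.253, 0.141, 0.0737, 0.108, 0.0957 and 0.205, in that order, with 1 array left out. Those of KDM4B and MMP2 ended without either hypoxia array of experiment 2, and the others without any 1 of its 4 arrays. The calls of WDR12, NOP58, ATP5F1B and TGFBI also ended without either normoxia array of experiment 1, and the TFRC call without any 1 of the 4 arrays of experiment 2 (up to 0.0809). The calls of WDR12, ATP5F1B and SLC7A11 ended without a level filter (adjusted p = 0.0606, 0.0525 and 0.0501), that of ATP5F1B also without probe sets that can bind several transcripts (adjusted p = 0.0515), that of SLC7A11 with the mean of its probe sets (adjusted p = 0.0775) and that of TGFBI after quantile normalization (adjusted p = 0.0562).

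Some squamous differentiation genes rose in experiment 2. Of the 34 on the list 11 were measured, so most of the programme was not seen. Of these 11, 5 rose and 1, PPL, fell, the same adjusted over the list alone (adjusted p = 0.00142; adjusted p = 0.401 with an estimated correlation). S100A8, an alarmin of stressed epithelium, rose by 1.41 (adjusted p = 0.000511). That list lost its call without probe sets that can bind several transcripts (adjusted p = 0.128). Unfolded protein and integrated stress response genes rose in 2 of 25, the same adjusted over the list alone (adjusted p = 0.00175; adjusted p = 0.28 with an estimated correlation): ATF3 by 1.30 (adjusted p = 0.00433, 0.058 without hypoxia replicate 1 and 0.182 with its second probe set) and DDIT3 by 0.74, named after its value was seen. Tricarboxylic acid cycle genes fell in 1 of 15, the same adjusted over the list alone (adjusted p = 0.0395; adjusted p = 0.418 with an estimated correlation), and that gene, IDH3B, was named after its value was seen. Sterol synthesis genes (adjusted p = 0.0397; adjusted p = 0.365 with an estimated correlation) and autophagy and lysosome genes (adjusted p = 0.046; adjusted p = 0.394 with an estimated correlation) were called with 0 of 16 and 0 of 19 members called, counts the same adjusted over the list alone, and medians of 0.08 each. The last 3 calls ended in several settings. Adjusted p for the tricarboxylic acid cycle list was 0.0805 without normoxia replicate 1, 0.0749 without hypoxia replicate 1, 0.0506 with the mean of probe sets and 0.0633 without probe sets that can bind several transcripts. For the sterol list it was 0.127 without normoxia replicate 2, 0.0761 without hypoxia replicate 1, 0.0613 after quantile normalization and 0.0506 with the mean of probe sets. For the autophagy list it was 0.155 without normoxia replicate 2, 0.0731 without hypoxia replicate 1 and 0.0515 without hypoxia replicate 2. It was also 0.0527 with the filter at log2 6, 0.0511 with values under log2 4 set to 4, 0.0618 after quantile normalization and 0.0535 without probe sets that can bind several transcripts. No call was made for the basal keratinocyte list (0 of 16; adjusted p = 0.0827), the Notch list (0 of 16; adjusted p = 0.066), the G2/M list (0 of 28; adjusted p = 0.109) or the p53 list (0 of 16; adjusted p = 0.886). DNA replication genes fell in 1 of 29, PRIM1, named after its value was seen, or 0 adjusted over the list alone (adjusted p = 0.0947). Interferon response genes rose in 1 of 22, OAS3 by 0.47, or 2 adjusted over the list alone (adjusted p = 0.0517). MAPK and EGFR feedback genes rose in 1, DUSP1 by 0.86, and fell in 1 of 17, or 1 and 2 adjusted over the list alone (adjusted p = 0.143). With experiment 2 fitted alone, limma's camera at the preset correlation called the Notch, G2/M, DNA replication, interferon and MAPK lists. Adjusted p was 0.0316, 0.0205, 0.0245, 0.0481 and 0.0414, in that order. With an estimated correlation none of them was called. The lack of a call for these lists thus depends on the spread shared with experiment 1. The DUSP1 call (adjusted p = 0.00589) ended without either hypoxia array of experiment 2 (up to 0.0664) and the OAS3 call (adjusted p = 0.0254) without any 1 of its 4 arrays (up to 0.168). At an unadjusted p under 0.05 in limma the members numbered 4 in the basal list, 6 in the Notch list, 3 in the G2/M list, 3 in the p53 list, 2 in the sterol list and 5 in the autophagy list. For the basal, Notch, G2/M and p53 lists the counts were the same adjusted over the list alone.

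**Figure D2:**
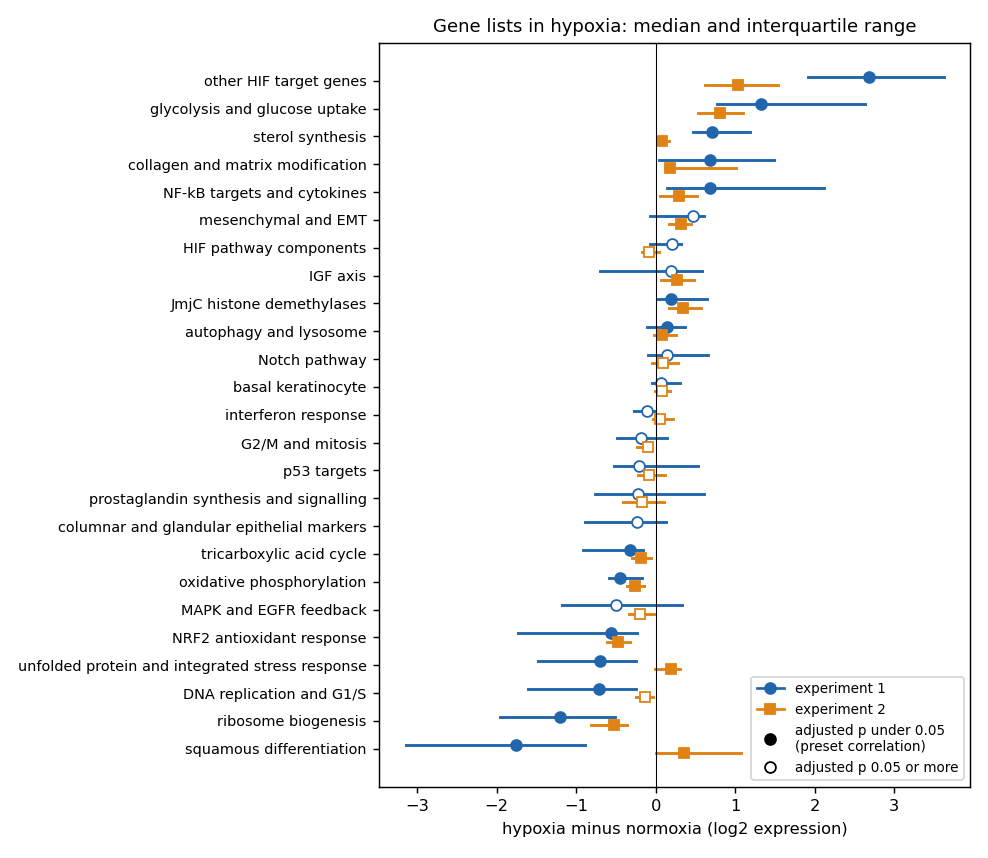
Median (points) and interquartile range (lines) of the log2 difference, hypoxia minus normoxia, over the measured genes of each list, with circles for experiment 1, squares for experiment 2 and filled symbols for adjusted p under 0.05. The HIF target list has the highest median in both experiments, 2.68 and 1.03, and the squamous differentiation list lies at -1.75 in experiment 1 and 0.36 in experiment 2.

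Which changes did the experiments share? Over both experiments the mean response was led by HIF target and glycolysis genes, and IGFBP3 was also among the shared rises. In the mean of the 2 within-experiment differences 1381 genes were higher and 2205 lower, of 8487. A gene that changed in 1 experiment alone can pass here, so these are not counts of shared changes. The counts were 353 and 333 in an additive fit, and 993 and 1423 without hypoxia replicate 1 of experiment 2. ANKRD37 had a mean rise of 6.39 log2 units, EGLN3 of 5.79 and IGFBP3 of 3.16 (adjusted p = 5.95e-07). With values under log2 4 set to 4 the rises of ANKRD37 and EGLN3 were 5.55 and 4.99. In the additive fit, where a change that differs between the experiments adds to the spread, the calls of EGLN3 (adjusted p = 0.0591), PDK1 (adjusted p = 0.0536) and 12 others named ended: PPP1R3C, PTGES, MAT2A, PRMT3, TFRC, ODC1, ISG20L2, ASNS, EREG, PRMT6, SRM and SRPRB (adjusted p from 0.0515 to 0.0999). The HIF target list (adjusted p = 7.52e-22; adjusted p = 0.0765 with an estimated correlation), the glycolysis list (adjusted p = 1.24e-15; adjusted p = 0.0765 with an estimated correlation) and the sterol list (adjusted p = 2.86e-07; adjusted p = 0.104 with an estimated correlation) were higher in the mean. The sterol list had a mean change of 0.78 in experiment 1 and 0.10 in experiment 2, where 0 of 16 members were called, so its mean rests mostly on experiment 1. The NRF2 list, which holds antioxidant defence genes, was lower (adjusted p = 9.86e-05; adjusted p = 0.255 with an estimated correlation). Across 8487 genes the log2 differences of the experiments correlated with Pearson r 0.449 and Spearman rho 0.411, and the major axis slope of experiment 2 on experiment 1 was 0.182. Genes are not independent replicates, so no p is given for these. Of 331 genes called in both experiments, 299 (90.3%) changed in the same direction, 9 of them with both groups under log2 4 in an experiment. Genes higher in both numbered 204, against 55.4 if the calls were independent, and genes lower in both 95, against 76.2.

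Which responses differed between the experiments? On the probe sets used, the HIF target genes EGLN3, ANKRD37 and PDK1, the chemokine CXCL8 and the chaperone HSPA6, a heat shock protein, rose more in experiment 1. MMP9 and, on its measured values, IGFBP3 had the larger change in experiment 2. The response differed for 2227 genes, with 1321 differences positive and 906 negative (experiment 2 minus experiment 1). Without 1 array in turn the number ran from 1289 to 2713, and with a replicate block it was 1402. The 10 with the largest size were KRTAP19-1 at -8.54 (adjusted p = 2.24e-07), EGLN3 at -8.02 (adjusted p = 5.77e-06), CXCL8 at -7.18, ANKRD37 at -7.09, HSPA6 at -6.56, PDK1 at -6.37, PTGES at -6.15, MAT2A at 6.14, WFDC5 at -6.11 and PAFAH1B1 at 6.01. Each of these has a group under log2 4, so the sizes and their order are not exact: with values under log2 4 set to 4 they were, in that order, -7.71, -8.20, -5.68, -5.40, -6.39, -5.56, -6.67, 5.45, -6.14 and 5.17. For CXCL8, PDK1, PTGES and PAFAH1B1 another probe set above log2 4 changed less than 1/2 as much, or oppositely, in experiment 1. Their differences thus depend on the probe set used. IGFBP3 differed by 1.68 (adjusted p = 0.000252), but it went from 13.33 to 15.65 in experiment 1, where the highest value on the hypoxia arrays was 16.50 and 16.52, against 6.44 to 10.44 in experiment 2. Saturation in experiment 1 was not tested, so the size and direction of that difference are open. MMP9 differed by 3.42 (adjusted p = 0.00065) and SLC2A1 by 0.52 (adjusted p = 0.0126). The second probe set of SLC2A1 went the other way, with 2.18 in experiment 1 and 1.84 in experiment 2, so no direction is given for its difference. Of the genes called in both experiments, 32 went in opposite directions, 2 of them with both groups under log2 4 in an experiment. Among the other 30 was S100A8, which differed by 4.61 (adjusted p = 5.77e-06). Its normoxia mean was 13.36 in experiment 1 and 6.79 in experiment 2. The differences were negative in 24 and positive in 1 of 30 other HIF target genes, or 25 and 1 adjusted over the list alone (adjusted p = 5.27e-14; adjusted p = 0.174 with an estimated correlation). They were negative in 10 and positive in 1 of 23 glycolysis genes, or 12 and 1 adjusted over the list alone (adjusted p = 8.99e-06; adjusted p = 0.174 with an estimated correlation). For sterol synthesis they were negative in 10 of 16, or 13 adjusted over the list alone (adjusted p = 7.11e-06; adjusted p = 0.174 with an estimated correlation). Squamous differentiation differences were positive in 6 of 9, the same adjusted over the list alone (adjusted p = 9.45e-05; adjusted p = 0.351 with an estimated correlation). Unfolded protein and integrated stress response differences were positive in 13 and negative in 3 of 23, or 16 and 3 adjusted over the list alone (adjusted p = 0.000202; adjusted p = 0.174 with an estimated correlation). DNA replication differences were positive in 8 of 24, or 8 and 1 negative adjusted over the list alone (adjusted p = 0.00687; adjusted p = 0.547 with an estimated correlation, and 0.0771 with values under log2 4 set to 4). NF-kB differences were negative in 4 of 12, or 6 adjusted over the list alone (adjusted p = 0.00687; adjusted p = 0.456 with an estimated correlation), and 0.41 without probe sets that can bind several transcripts. Collagen differences were negative in 6 and positive in 1 of 13, the same adjusted over the list alone (adjusted p = 0.018; adjusted p = 0.522 with an estimated correlation), with adjusted p = 0.0617 without normoxia replicate 1 of experiment 2. The collagen call also ended without probe sets that can bind several transcripts (mean -0.27; adjusted p = 0.189), without a level filter (adjusted p = 0.108) and after quantile normalization (adjusted p = 0.0513).

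**Figure D3:**
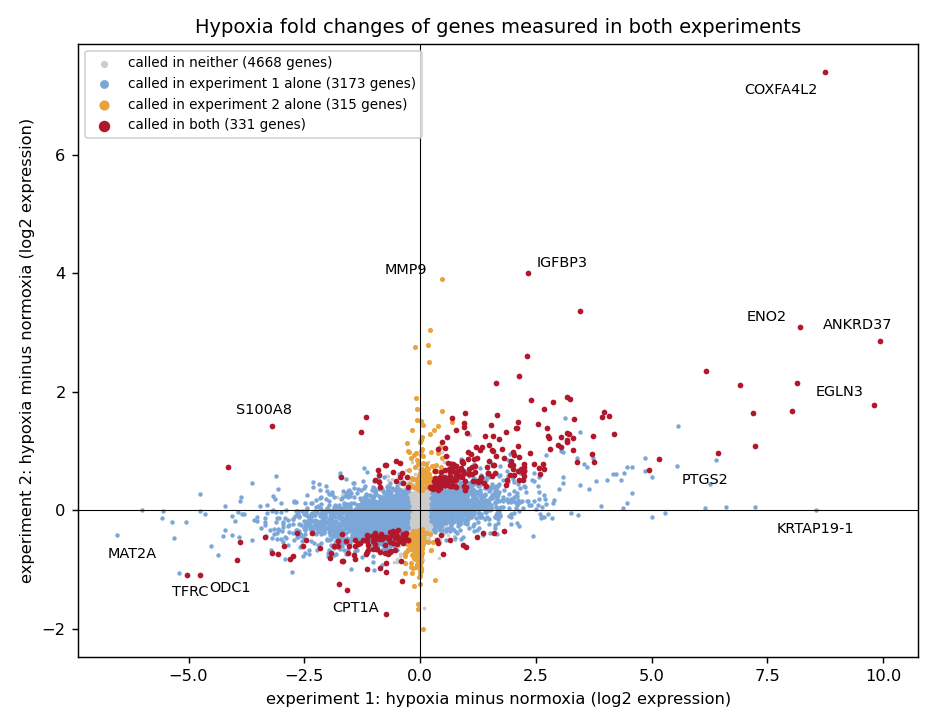
Each point is a gene tested in both experiments, with the log2 difference, hypoxia minus normoxia, in experiment 1 on the x axis and in experiment 2 on the y axis, coloured by where it was called. Most of the 331 genes called in both lie in the quadrants where the directions match, and IGFBP3 and MMP9 are higher on the y axis than on the x axis.

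The prostaglandin, insulin-like growth factor (IGF) and HIF pathway genes were followed by name. Prostaglandins are lipid signals made by PTGS2 (cyclooxygenase) and PTGES and broken down by HPGD. In experiment 1 PTGS2 rose 46.6-fold (5.54 ± 0.40 log2 units; adjusted p = 8.03e-05) and HPGD was at least 12.8-fold lower (adjusted p = 3.79e-05), with CBR1 at -1.17. HPGD and PTGES each have another probe set above log2 4 that changed less than 1/2 as much, or oppositely, in experiment 1. In experiment 2 PTGS2 changed by 0.75 (adjusted p = 0.309), and the difference between the experiments was -4.80 (adjusted p = 0.00165). PTGES and HPGD lay under log2 4 in both groups of experiment 2, so no direction is given for them there. The prostaglandin list had 3 rises and 4 falls among 11 genes in experiment 1, the same adjusted over the list alone and not independent evidence, since the list was drawn up knowing of work on hypoxia in these cells (adjusted p = 0.998). Its median was -0.22 and its mean 0.49, so they differ in sign, and the test with a preset correlation pointed down while the other list tests pointed up. In experiment 2 the list of 10 held the PTGES call alone, or 1 rise and 2 falls adjusted over the list alone (adjusted p = 0.567). IGFBP3 rose 16.1-fold in experiment 2 and by 2.32 ± 0.08 (adjusted p = 5.74e-06) in experiment 1, where the receptor IGF1R rose by 0.95 and the adaptor IRS1 changed by -1.03. The IGF list had 4 rises and 3 falls of 8 in experiment 1 (adjusted p = 0.586; median 0.19, mean -0.03), the same adjusted over the list alone and not independent evidence. In experiment 2 it had 2 rises of 8, or 3 rises and 1 fall adjusted over the list alone, not independent evidence either (adjusted p = 0.00566; adjusted p = 0.203 with an estimated correlation), and adjusted p = 0.244 without probe sets that can bind several transcripts. HIF1A, the oxygen-regulated subunit of HIF, changed by -0.70 in experiment 1 (adjusted p = 0.000676) and by -0.14 in experiment 2 (adjusted p = 0.364). EPAS1 changed by 0.40 (adjusted p = 0.0187, 0.0678 with the mean of its probe sets, and up to 0.0769 without either normoxia array or hypoxia replicate 1 of experiment 1) and -0.08 (adjusted p = 0.711), and ARNT, the partner subunit, by 0.20 (adjusted p = 0.244) and -0.18 (adjusted p = 0.414). CITED2, which competes with HIF for its coactivator, rose at least 3.90-fold in experiment 1 and by 0.69 in experiment 2 (adjusted p = 0.0103), the latter with adjusted p up to 0.0977 without normoxia replicate 2 or either hypoxia array of experiment 2. The HIF pathway list had 3 rises and 2 falls of 11 (adjusted p = 0.238) and 1 rise of 12 (adjusted p = 0.856), the same adjusted over the list alone. VEGFA rose by 0.54 in experiment 1, and its change of 0.45 in experiment 2 did not pass (adjusted p = 0.0757). CA9 had no value in the table.

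RNA quality and the markers of other cells were read beside these groups. The 3' minus 5' signal of GAPDH, a glycolytic gene used as a degradation control, was 0.05 ± 0.06 log2 units in normoxia and 0.10 ± 0.05 in hypoxia in experiment 1 (SD, n = 2), and 0.31 ± 0.04 and 0.29 ± 0.01 in experiment 2. That of ACTB was 0.43 ± 0.04 and 0.61 ± 0.09 in experiment 1, and 0.77 ± 0.08 and 0.78 ± 0.12 in experiment 2. In experiment 1 ACTB thus moved with hypoxia, beside the falls of the squamous, replication and ribosome biogenesis genes. The median of the hybridisation spikes bioB, bioC, bioD and cre in experiment 1 was 8.13 and 7.73 in normoxia and 9.16 and 10.64 in hypoxia, and in experiment 2 it was 8.54 and 8.68 against 8.55 and 8.51. Columnar and glandular epithelial markers fell in 2 of 5 in experiment 1, the same adjusted over the list alone (adjusted p = 0.66): KRT18, a simple epithelium keratin, by -0.88 (adjusted p = 0.00279), and AGR2, named after its value was seen. Of 4 measured in experiment 2, 0 were called and 2 had an unadjusted limma p under 0.05, or 1 fell adjusted over the list alone, and KRT8 and KRT19 changed by 0.16 and 0.12 in experiment 1. Of the fibroblast markers 2 were measured, with 1 fall in experiment 1 and 1 rise in experiment 2: POSTN changed by -1.21 in experiment 1 (adjusted p = 0.00447, and 0.064 with experiment 1 fitted alone), and the collagen gene COL1A1 rose by 1.68 in experiment 2 (adjusted p = 0.00583; other probe sets above log2 4 at 1.76 and 0.22). Of the endothelial and leukocyte markers 0 passed the level filter with values.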

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

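The tests of replicate spread, of dim probe sets and of the oxygen level were chosen only after the results were seen. The test of target amount and the count of splits were fixed earlier.

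The hypoxia response differed between the experiments for 2227 genes in a test of the difference itself (1289 to 2713 without 1 array in turn, and 1402 with a replicate block). The list means differed (experiment 2 minus experiment 1, log2) by -1.17 for glycolysis, -1.99 for other HIF targets, -0.67 for sterol synthesis, -1.36 for NF-kB targets and -0.55 for collagen modification, and by 1.89 for squamous differentiation, 0.80 for DNA replication and 0.99 for the unfolded protein and integrated stress response. Single genes with the largest differences were KRTAP19-1 (-8.54), EGLN3 (-8.02), CXCL8 (-7.18), ANKRD37 (-7.09), HSPA6 (-6.56), PDK1 (-6.37), PTGES (-6.15), MAT2A (6.14), WFDC5 (-6.11) and PAFAH1B1 (6.01), sizes that are not exact because each rests on a group under log2 4. For CXCL8, PDK1, PTGES and PAFAH1B1 the size also depends on the probe set used, since another changed less than 1/2 as much, or oppositely, in experiment 1. S100A8 (4.61) fell in experiment 1, from 13.36 in normoxia to 10.16, and rose in experiment 2, from 6.79 to 8.20. KRT16 and DSC2, named after their values were seen, are the other squamous genes called in opposite directions. Their normoxia means were 14.06 and 13.42 in experiment 1 against 6.91 and 10.24 in experiment 2. Whether the control cultures differed in state was not tested. In data outside the gene comparisons, control probe sets for bacterial dap RNA were higher in hypoxia than in normoxia in experiment 1, AFFX-DapX-3_at by 3.27 and AFFX-r2-Bs-dap-3_at by 3.93. The 5' sets AFFX-DapX-5_at and AFFX-r2-Bs-dap-5_at changed by 0.64 and 0.17. The median of the 6 dap sets was 2.65 and 2.70 in normoxia and 4.01 and 4.44 in hypoxia. The median of the bioB, bioC, bioD and cre spikes lay 2.71 above the normoxia mean in hypoxia replicate 2 of experiment 1.

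More genes were called in experiment 1 (1378 higher and 2145 lower) than in experiment 2 (375 and 357). With each experiment fitted alone, so that they share no estimate of spread, the calls numbered 2200 and 1538 against 3523 and 732. The gap in counts was thus much smaller without the shared estimate, so part of it came with the shared fit. Experiment 1 still had more calls. Wider replicate spread in experiment 2 is excluded: replicate differences there had an SD of 0.185 and 0.165 (normoxia and hypoxia) against 0.252 and 0.332 in experiment 1. It would also leave the sizes of change alike, but among the 299 genes called the same way in both, the median ratio of experiment 2 to experiment 1 was 0.633 (95% bootstrap interval over genes, 2000 resamples, 0.571 to 0.670). This interval and the others in this paragraph treat genes as independent, which they are not. They hold no variation between arrays or cultures, so they may be too narrow. A stretch of dim probe sets by GCRMA would spare bright genes, but the SD of log2 changes in 2690 genes with a mean above log2 10 was 2.57 times as large in experiment 1 (2.36 to 2.78). Less target or other labelling on the hypoxia arrays of experiment 1 stays open: the difference between its hypoxia replicates, whose spikes differ, correlated with the hypoxia change at r 0.242 across 8588 genes (0.205 to 0.275), between the values set in advance for and against. The oxygen level, the biological difference that the design names, may account for the larger response and stays untested, because the sources agree on the level in 0 of the 2 experiments, and level and experiment cannot be told apart.

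For the genes called in the mean of both experiments, the splits of the arrays cannot decide whether chance is the source of the count. In an additive fit, not the fit that gave 1381 and 2205 calls, the real split called 686 genes. Of the 34 splits of the 8 arrays 1, the real one, called as many, with 1 gene in the highest of the others. Many splits divide an experiment unequally, which the design could not give, and the rest are too few to go under the share set in advance. Splits that mix hypoxia with normoxia also take the hypoxia effect into their spread, so few calls are likely in them. The split that equals the experiments could not be fitted.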

How the results depend on the processing

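The crossed replicate block and the fit of only genes with values in all 8 arrays were chosen after seeing the data. Apart from the settings named here, counts stayed within 1.5 times the reported ones, and the cause of each change was not tested unless stated. Without 1 array in turn counts fell or rose; without either hypoxia array of experiment 1, experiment 2 had 1054 calls against 732. Over these settings, experiment 1 had 1119 to 1483 genes higher, 1713 to 2396 lower and 12 to 14 lists; experiment 2 had 70 to 495 higher, 22 to 559 lower and 12 to 17 lists; the mean had 993 to 1506 higher and 1423 to 2538 lower; the difference had 1289 to 2713 genes and 7 to 8 lists; and the correlation ran from 0.429 to 0.453. A stricter rule calls fewer genes by construction: at 2-fold 513 and 907 in experiment 1, 105 and 28 in experiment 2, 236 and 338 in the mean and 1088 for the difference; at adjusted p under 0.01, 120 and 42 in experiment 2, 843 and 1249 in the mean and 1082 for the difference. Testing every probe set raised the counts, since probe sets were counted, to 2494 and 3351, 566 and 575, 2442 and 3432, and 3653, with a correlation of 0.413. Without probe sets that can bind several transcripts 899 genes were higher in experiment 1, 9 lists were called in experiment 2 and the correlation was 0.415. Fitted alone, experiment 1 had 1276 genes lower and experiment 2 had 637 higher and 901 lower. Quantile normalization gave 738 and 709 in experiment 2. Same-numbered deviations correlated at r -0.163 in experiment 1 and -0.075 in experiment 2. With 2 arrays per group this cannot settle whether the replicate numbers pair the arrays. A replicate block gave 86 and 24 in experiment 2 and 1402 for the difference, and the crossed block 228 lower in experiment 2. The additive fit gave 353 and 333 for the mean. The correlation was 0.465 for the filter at log2 6, 0.430 with values under log2 4 set to 4 and 0.467 with the mean of a gene's probe sets. With an estimated correlation 0, 0 and 0 lists were called in experiment 1, experiment 2 and the difference; fry called 16 for the difference. Under fry, which does not compare a list with other genes, the prostaglandin list of experiment 1 pointed up (mean 0.49; adjusted p = 0.00133), as did the MAPK list (mean -0.19; adjusted p = 0.012). Of 7199 comparisons of single genes and lists 6780 kept direction and side of the threshold, 290 lost the call, 127 gained it and 2 reversed. Median centring moved the median gene of experiment 1 by 0.114 and the share of calls that were higher from 39.1% to 49.0%; no called list changed direction with it or with quantile normalization. In experiment 1, 60 rises and 162 falls have 1 group under log2 4, where the size is a bound, and 19 and 91 have both.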

Other observations

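The 3 gene lists here, all that were tried, were drawn up after the largest changes of experiment 1 had been seen, to ask whether HSPA6, ASNS and MAT2A moved with their relatives; what each test would show was set down before its result was seen. Adjusted p is over these 3 lists, with a preset and with an estimated correlation.

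HSPA6, a stress-inducible chaperone, rose at least 84.8-fold in experiment 1. If it were part of a rise of heat shock chaperones, the others would rise as a list, but among 16 of them 4 rose and 10 fell, with a median of -0.34 (quartiles -0.56 and 0.36; adjusted p = 0.443, and 0.652 with an estimated correlation). DNAJB1 rose by 1.67 and DNAJB6 by 2.01, so single chaperones went the way of HSPA6, and the list as a whole did not.

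ASNS is switched on by the amino acid response, as are most aminoacyl-tRNA synthetases, which charge transfer RNA. In experiment 1, 15 of 16 synthetases fell and 0 rose, with a median of -1.23 (quartiles -1.50 and -0.43; adjusted p = 1.47e-05, and 0.522 with an estimated correlation), among them AARS1 at -1.85, IARS1 at -1.84 and EPRS1 at -1.72. This is consistent with lower expression of amino acid response genes in that experiment, as a hypothesis, since other losses of growth-related RNA were not excluded and the call rests on the preset correlation. In experiment 2 no synthetase of 17 was called (adjusted p = 0.0473 for the list, and 0.749 with an estimated correlation), and the difference between the experiments was positive in 8 of 16 (adjusted p = 0.000201, and 0.768 with an estimated correlation).

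MAT2A, PRMT3 and PRMT6 make or use the methyl donor S-adenosylmethionine. The other arginine methyltransferase and methionine cycle genes fell in 8 and rose in 1 of 15 in experiment 1, with a median of -0.53 (quartiles -0.84 and -0.30; adjusted p = 0.0364, and 0.522 with an estimated correlation). MTRR was at least 9.24-fold lower, while the spermine synthase gene SMS rose by 1.13; MTAP, counted among the 8, had both groups under log2 4. The list thus fell beside MAT2A at the preset correlation alone, and its median fall was far smaller than that of MAT2A, which was at least 58.1-fold lower. Whether a fall of the pathway as a group underlies the change of MAT2A was not tested. In experiment 2 the list was not called (1 rise of 16; adjusted p = 0.0841).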
